A study of Morone chrysops x Morone saxatilis with 6 samples.

How the data were processed

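Hybrid striped bass, the cross of white bass with striped bass, were grown in communal ponds, per the labels, and RNA was taken from the liver of the largest and of the smallest fish. Per the labels, RNA from several fish was pooled in equal amounts before library preparation with an Illumina TruSeq kit for RNA. The number of fish per pool is not given in the sources used here. A library therefore holds a pool of fish and not 1 animal. The 6 libraries form 2 groups of 3, large and small, taken from the growth label of each sample. The description label numbers the libraries 1 to 3 within each group, while the titles number them 1 to 6 across both groups, so that the labels do not say that equal numbers belong together. The labels call the libraries biological replicates without saying how the pools were drawn, so p-values measure the spread between these pools.

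The authors deposited 1 table of estimated counts, with a row for each of 38047 coding sequences and a column for each library. Per the submitters' processing notes, Trim Galore 0.4.3, Bowtie2 2.3.1, eXpress 1.5.1 and DESeq2 were used, but their roles and settings are not given in the sources used here. The values were taken to be expected counts because eXpress estimates counts by sharing reads between similar sequences, and all of the deposited values were whole numbers (0 were not), so that no rounding was needed. Sharing of reads means that coding sequences from near-identical gene copies, or from the 2 parental copies of a gene, cannot be assumed to be counted separately. The table names the rows only by a running number (HSB_liver_CDS followed by the number). No gene name, annotation or coordinate was used here, so 33 gene lists chosen before the data were examined (metabolic pathways, immune and stress genes and cell type markers) could not be matched (0 lists matched, since 0 identifiers are paired with a name), and no list was tested. The coding sequences are therefore named by identifier, and the rule fixed beforehand for unnamed rows gave 2 identifiers in each direction, ordered by p where none passed the threshold.

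Total counts were 5327580, 4783800 and 19625891 in large libraries 1, 2 and 3, and 8892682, 2434421 and 3491954 in small libraries 1, 2 and 3. A count of 0 allows up to 3 counts, which is 0.153 CPM (counts relative to the library total) in the deepest library and 1.23 CPM in the shallowest. Intervals on single shares are exact 95% binomial intervals. They cover counting error only, since reads copied by PCR are not independent molecules.

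The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 (robust fit), large minus small, with TMM scaling, the filterByExpr filter (18135 coding sequences kept, 19912 left out) and Benjamini-Hochberg adjustment, with an adjusted p of 0.05 as threshold. Standard errors of log2 fold changes were derived from the F statistic. Principal components and sums of squares used log2 CPM with a prior count of 2. CPM of single coding sequences are TMM-scaled. The alternatives fixed before the data were examined were DESeq2 1.42.0, limma 3.58.1 with voom, other scaling factors, filters and thresholds, a minimum fold of 1.5, a fit with the replicate number as a block, and leaving out each library in turn. DESeq2 and voom with the block, thinning of all libraries to 2434421 counts, leaving out both libraries of a number, and another tuning of the filter in DESeq2 were added after seeing the data.

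Whether the numbers pair the libraries was decided by a limit of 0.1 set beforehand, but the correlations were read at the same time as the calls of the fits with and without the block, not ahead of them. The deviations of log2 CPM from the group means correlated between the large and the small library of the same number at 0.72 for number 1, 0.19 for number 2 and 0.59 for number 3. All 3 were above the limit, so the numbers were treated as pairing the libraries. Large library 3 with small library 2 (0.20) and large library 2 with small library 3 (0.11) were also above it. The limit alone therefore does not single out the pairing of numbers 2 and 3 used in the fits with the block. The pairing thus comes from these values, since the labels do not say what a number stands for. Of the 6 libraries, 5 deviated most like the library of their own number in the other group, and small library 2 deviated most like large library 3. Deviations from a group mean cancel out within the group, which lowers correlations between its libraries (-0.73 to -0.16 here). A best match in the other group was therefore largely fixed in advance, and only the choice among the libraries of that group bears on pairing.

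The tests were tried on simulated data: 5 datasets were drawn for the 18135 tested coding sequences from the fitted means per replicate number and the dispersions of the edgeR fit with the block, with 200 sequences changed 2-, 4- or 8-fold between large and small. Replicate number took a mean of 74.3% of the sum of squares in these datasets, more than the 68.4% in the real libraries. The median estimate for a true log2 change of 2 was 1.98 in edgeR without the block and 1.97 with it. Without the block edgeR recovered 0% of the 4-fold and 0% of the 8-fold changes. With the block it recovered 5.67% of the 2-fold, 54.3% of the 4-fold and 76.7% of the 8-fold changes. DESeq2 without the block recovered 0% of the 2-fold, 22.1% of the 4-fold and 58.5% of the 8-fold changes. With the block DESeq2 recovered 13.4%, 63.3% and 86.4% in that order. In simulated libraries without variation between numbers, edgeR without the block recovered 54.6% of the 4-fold and 83.6% of the 8-fold changes. Over the 5 simulated datasets 57 of 511 calls were false for edgeR with the block (a mean of 11.4 per dataset). For DESeq2, 11 of 278 were false without the block (2.2 per dataset) and 155 of 697 with it (31 per dataset). In the libraries simulated without variation between numbers, 45 of 525 calls of edgeR without the block were false (9 per dataset). The recovered shares, the false shares and the false counts per dataset all depend on the number of changes put in. They therefore do not give the number of false calls among real calls, or the share of real changes found.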

Results

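Liver RNA of hybrid striped bass at the upper and lower ends of growth was compared by sequencing 6 pooled libraries, 3 from large and 3 from small fish. Between 2434421 and 19625891 counts per library fell on the 38047 coding sequences of the table, and 544 of these had no count in any library. The question set by the design is which liver transcripts differ between the largest and the smallest fish grown in communal ponds.

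The share of the most abundant transcript was higher in large fish within each replicate number, a difference that did not pass an exact test. HSB_liver_CDS_35983, the most abundant on average, took 5.07% ± 1.43 (SD, n = 3) of all counts in the large and 4.0% ± 0.52 (SD, n = 3) in the small group. In the large and the small library the share was 3.67% and 3.52% for number 1, 6.54% and 4.55% for number 2, and 5.0% and 3.92% for number 3. Single libraries ranged from 3.52% (exact 95% binomial interval 3.51% to 3.53%) in small library 1 to 6.54% (6.52% to 6.56%) in large library 2. The 10 most abundant coding sequences of a library together took 14.5% ± 1.25 (SD, n = 3) of the counts in the large and 13.7% ± 1.33 (SD, n = 3) in the small group. After all libraries had been thinned to the 2434421 counts of the shallowest, 27332 ± 714 (SD, n = 3) coding sequences were detected in the large and 26499 ± 1293 (SD, n = 3) in the small group. These 2 measures were higher in the large library for 2 of the 3 numbers. Two-sided exact permutation tests over all 6 libraries gave p = 0.3, 0.5 and 0.4 in the order given, and exact tests that exchanged large and small within each number, chosen after seeing the data, gave 0.25, 0.5 and 0.5, with a Benjamini-Hochberg value of 0.5 throughout. The smallest p these tests allow is 0.1 over all libraries and 0.25 within numbers.

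On average the expression profiles were grouped by replicate number more than by growth. The large and the small library of the same number correlated at a mean Pearson r of 0.89 in log2 CPM across coding sequences (range 0.85 to 0.92, 3 pairs), against 0.77 for libraries of the same growth group (range 0.68 to 0.87, 6 pairs). Number 2 was an exception: its 2 libraries correlated at 0.85, large libraries 2 and 3 at 0.87, and small library 2 with large library 3 at 0.86. Coding sequences are not independent replicates, so no p is attached to these values. The first principal component held 53.2% of the variance. Its scores were -114 and -120 for the large and small libraries numbered 1, 20.9 and 40.6 for those numbered 2, and 77.4 and 95.1 for those numbered 3. Replicate number took 68.4% of the sum of squares around the mean of each coding sequence, and growth group took 11.7%. Their shares of the degrees of freedom are 40% and 20%. The closest pair of libraries had a chi-square per degree of freedom of 13.9, where sampling noise alone gives about 1, so no pair was treated as the same library.

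**Figure D1:**
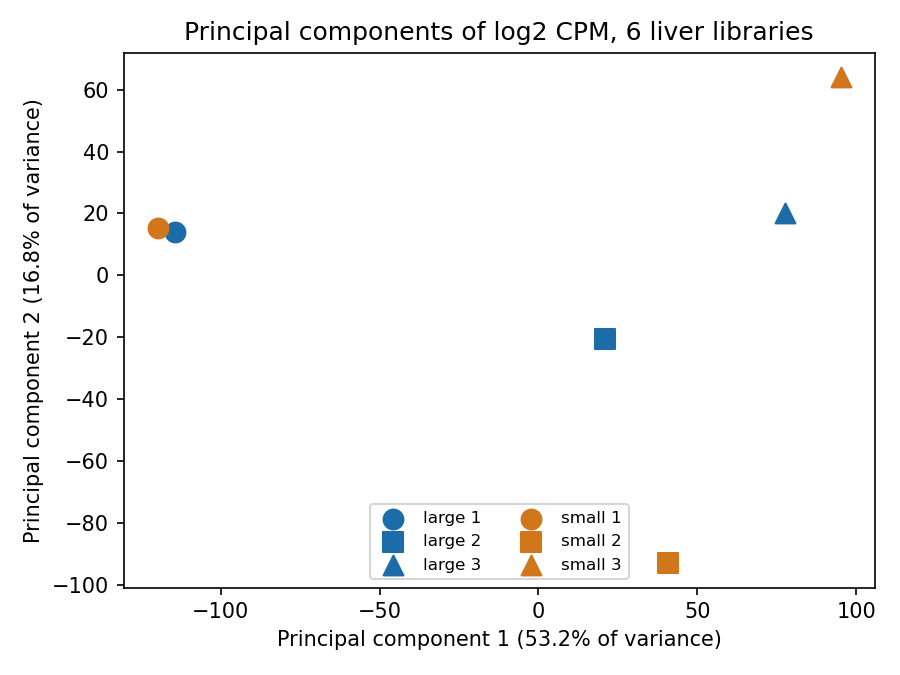
Scores of the 6 libraries on the first (x axis, 53.2% of the variance) and second (y axis, 16.8%) principal component of log2 CPM; colour marks the growth group and the marker shape the replicate number. The large and small libraries numbered 1 lie together at -114 and -120 on the first component, while those numbered 2 and 3 have positive scores.

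Values of 2 abundant transcripts that differed between number 1 and the others were as follows. HSB_liver_CDS_36538 stood at 2398 and 2122 CPM in the large and small libraries numbered 1, at 8998 and 10033 CPM in those numbered 2 and at 10311 and 11113 CPM in those numbered 3. HSB_liver_CDS_31197 was at 16992 and 22551 CPM in the libraries numbered 1, at 13725 and 10176 CPM in those numbered 2, and at 10332 and 9418 CPM in those numbered 3. They do not stand for abundant transcripts in general, since both were chosen after their values were seen, as the most abundant coding sequences called in each direction when number 1 was set against numbers 2 and 3 (edgeR with growth group in the model, adjusted p = 0.0056 for HSB_liver_CDS_36538 and 0.040 for HSB_liver_CDS_31197). That contrast called 3747 of 18135 coding sequences, 1632 higher and 2115 lower in number 1.

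Between large and small fish, no coding sequence passed the threshold in edgeR, while the counts from DESeq2 and voom depended on the block. The quasi-likelihood test of edgeR called 0 of 18135 coding sequences at an adjusted p of 0.05, and the smallest adjusted p was 1.0. At an unadjusted p under 0.05 there were 194 coding sequences (1.07%), where an even spread of p-values would give 907. That count was 438 of 18513 without small library 1, 383 of 18538 without large library 1 and 117 of 20130 without large library 2, with 0 calls each time. With the replicate number as a block the count of calls was again 0, the smallest adjusted p was 0.93, and 907 coding sequences (5.0%) lay under an unadjusted 0.05. DESeq2, which the submitters' processing notes name, called 1 coding sequence without the block, with 466 under an unadjusted 0.05 (1.25%, where an even spread would give 1867). With the block DESeq2 called 51, of which 25 were higher and 26 lower in large fish, with 806 under an unadjusted 0.05 (2.15%, where an even spread would give 1875). Limma voom called 0 without the block and 1 with it, with 444 (2.45%) and 1591 (8.77%) under an unadjusted 0.05. In data simulated from the fitted means per number, the edgeR fit without the block recovered 0% of 8-fold changes. Replicate number took a mean of 74.3% of the sum of squares there, against 68.4% in the real libraries. The 0% may therefore understate recovery in the real data. The count of 0 in this fit does not bound the number of transcripts that differ. With the block edgeR recovered 76.7% of 8-fold, 54.3% of 4-fold and 5.67% of 2-fold changes in the simulated data. DESeq2 recovered 58.5% of 8-fold changes without the block and 86.4% with it. All these shares depend on the number of changes put in. The data were drawn with the dispersions of the edgeR fit with the block, which may favour that fit.

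**Figure D2:**
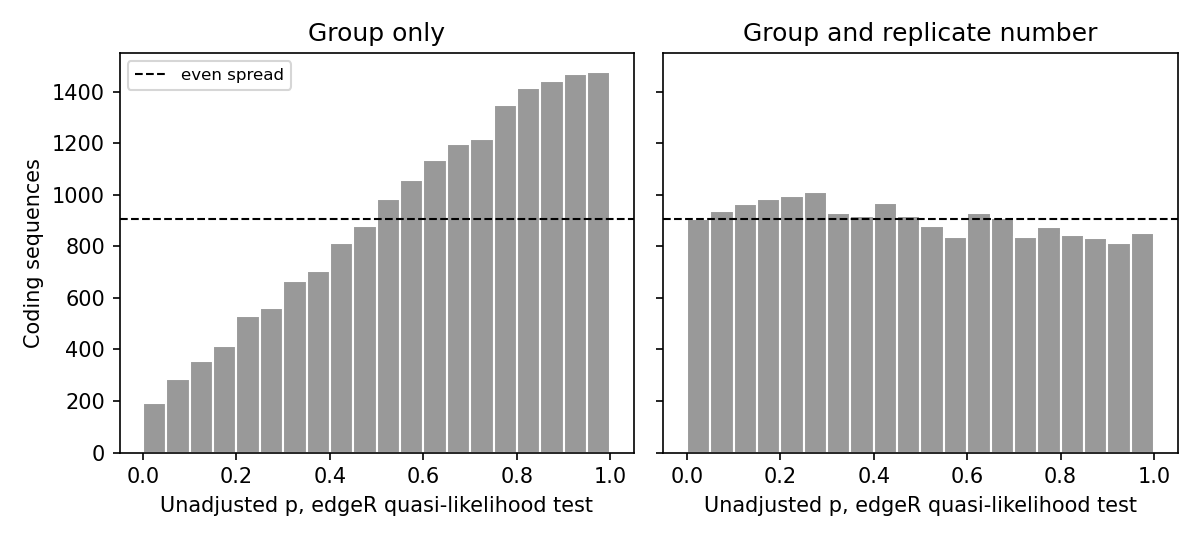
Number of coding sequences (y axis) by unadjusted p of the edgeR quasi-likelihood test of large against small (x axis, bins of 0.05), for the fit with growth group only (left) and with replicate number added (right); the dashed line is the even spread of 907 per bin. The lowest bin holds 194 coding sequences on the left and 907 on the right.

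Of the 2 coding sequences with the smallest p in each direction, HSB_liver_CDS_3407 was at 17.8 ± 11.6 CPM (SD, n = 3) in large and at 0.40 ± 0.17 CPM (SD, n = 3) in small fish. The log2 fold change was 5.55 (SE 0.82, edgeR adjusted p = 1.0 without and 0.93 with the block). Its counts were 169, 77 and 114 in the large libraries against 2, 1 and 2 in the small ones, a pooled rate ratio of 38.2 with a counting interval of 16.2 to 118. It was the 1 coding sequence that DESeq2 called without the block (adjusted p = 0.00075, and 4.8e-05 with the block). HSB_liver_CDS_25458 was at 6.33 ± 2.44 CPM (SD, n = 3) in large and 0.34 ± 0.06 CPM (SD, n = 3) in small fish, a log2 fold change of 4.16 (SE 0.67, edgeR adjusted p = 1.0). Its small libraries held 3, 1 and 1 counts, and the pooled rate ratio was 15.1 with a counting interval of 6.31 to 47.1. With the block its adjusted p was 0.93 in edgeR and 0.053 in DESeq2.

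In the other direction, HSB_liver_CDS_23211 was at 10.5 ± 1.88 CPM (SD, n = 3) in large and 41.3 ± 13.4 CPM (SD, n = 3) in small fish. Its log2 fold change was -1.97 (SE 0.36, edgeR adjusted p = 1.0). HSB_liver_CDS_26126 was at 2.83 ± 2.03 CPM (SD, n = 3) in large and 27.4 ± 10.6 CPM (SD, n = 3) in small fish, a log2 fold change of -3.24 (SE 0.68, edgeR adjusted p = 1.0). DESeq2 with the block gave adjusted p-values of 0.00053 for HSB_liver_CDS_23211 and 0.00033 for HSB_liver_CDS_26126, and without the block 0.17 and 0.056. EdgeR with the block gave an adjusted p of 0.93 for each. Without both libraries of number 1, 2 or 3, the DESeq2 fit with the block gave adjusted p-values of 0.11, 0.070 and 0.57 for HSB_liver_CDS_23211, which lost its call each time at log2 fold changes of -2.19, -1.83 and -1.78 (-1.94 with all libraries), and 0.0021, 0.070 and 0.014 for HSB_liver_CDS_26126, which lost it without number 2 at a log2 fold change of -2.47 (-3.35 with all libraries). In the same fits HSB_liver_CDS_3407 had adjusted p-values of 0.55, 0.0018 and 0.00012, losing its call without number 1 at a log2 fold change of 4.37 (5.46 with all libraries). These fits hold 4 of the 6 libraries. For HSB_liver_CDS_26126 the large and small libraries stood at 4.72 against 20.6 CPM for number 1, 0.69 against 39.7 CPM for number 2 and 3.09 against 22 CPM for number 3.

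**Figure D3:**
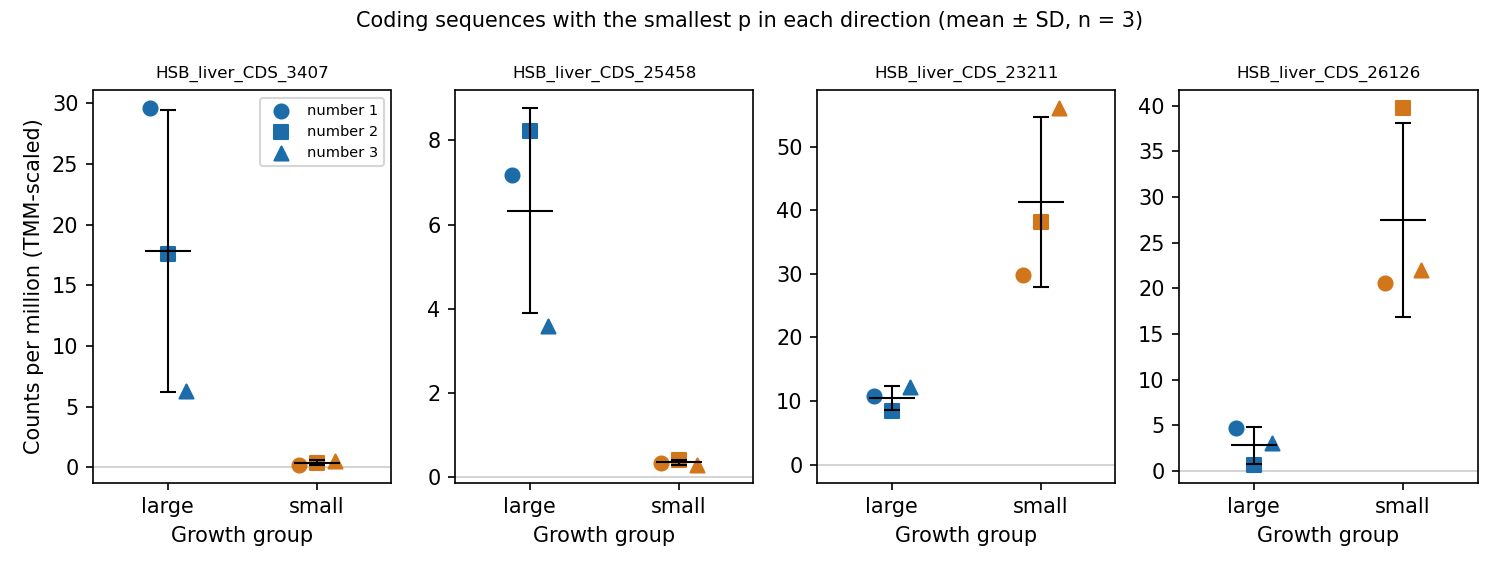
TMM-scaled CPM (y axes, one scale per panel) of the 2 coding sequences with the smallest p in each direction, in large and small fish (x axes); points are libraries, marker shape is the replicate number, and bars are mean ± SD (n = 3). HSB_liver_CDS_3407 averaged 17.8 CPM in large against 0.40 CPM in small fish, and HSB_liver_CDS_23211 averaged 10.5 against 41.3 CPM.

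The 51 coding sequences that DESeq2 called with the block had a median absolute log2 fold change of 2.45 (range 0.79 to 9.69), and 50 of them differed in the called direction within all 3 numbers. Of the 47 that edgeR also tested, 47 had an unadjusted p under 0.05 in edgeR with the block and 26 without it. These counts, and the shared direction, come from the libraries on which the 51 were selected and are not independent evidence for them. In the simulated data, with 200 sequences changed per dataset, 155 of 697 calls of this DESeq2 fit were false, a mean of 31 per dataset. DESeq2 without the block made a mean of 2.2. These counts depend on the changes put in and on simulating only the 18135 sequences that edgeR tested. They therefore do not give the number of false calls among the 51. When both libraries of a number were left out, DESeq2 with the block called 10 coding sequences without number 1 (7 shared with the 51), 33 without number 2 (16 shared) and 48 without number 3 (25 shared). Over all 18135 coding sequences, the difference between large and small had the same sign in all 3 numbers for 29.3%. Chance gives 25% only if rises and falls are equally likely and independent between numbers, which was not tested. The within-number differences, which share no library, correlated across coding sequences at r = 0.06 between numbers 1 and 2, 0.08 between 1 and 3 and 0.04 between 2 and 3.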

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

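The settings with DESeq2 or voom and the block, the other filter tuning, thinning and the leaving out of a number were chosen after seeing the data. Of 27 other settings, 19 also gave 0 coding sequences between large and small fish. These included voom, other scaling factors and filters, thresholds of 0.01 and 0.1, a minimum fold of 1.5, edgeR with the replicate block, thinning to equal total counts, the 6 fits that each left out 1 library, and the fit without both libraries numbered 1. The settings with calls were DESeq2 (1), DESeq2 with its filter tuned to 0.1 (3), voom with the replicate block (1), DESeq2 with the block (51, or 49 with the filter tuned to 0.1), and DESeq2 with the block without number 1 (10), 2 (33) or 3 (48). The thresholds of 0.01 and 0.1 and the minimum fold of 1.5 could add no calls. The smallest adjusted p of the main edgeR fit was 0.9999. Most other settings with 0 calls vary that fit, which recovered 0% of simulated 8-fold changes. These do not bound how many transcripts differ. EdgeR with the block, also at 0 calls, recovered 76.7% with 200 changes put in. The cause of the difference between tools was not tested. The 3 calls of DESeq2 without the block and with the filter tuned to 0.1 were HSB_liver_CDS_3407, HSB_liver_CDS_26126 and HSB_liver_CDS_9573, and voom with the block called HSB_liver_CDS_18399. The last of the 3 and HSB_liver_CDS_18399 are named after their values were seen: HSB_liver_CDS_9573 had 143, 16 and 26 counts in the large and 0 in each small library, and HSB_liver_CDS_18399 had 0, 13 and 226 counts in the large and 67, 147 and 655 in the small libraries. The log2 fold changes of the 4 coding sequences named by rule kept their sign in every setting that tested them, with ranges of 4.37 to 6.49 for HSB_liver_CDS_3407, 3.55 to 4.42 for HSB_liver_CDS_25458, -2.19 to -1.68 for HSB_liver_CDS_23211 and -4.09 to -2.47 for HSB_liver_CDS_26126. Their adjusted p-values ran up to 1.0 for all 4 and down to 4.8e-05, 0.053, 0.00053 and 0.00033 in that order. These 4 were chosen by small p from the same libraries, so their unchanged signs are not independent evidence for them. The share of the first principal component ranged from 48.5% to 62.8% when 1 library was left out. It was 62.8% without small library 2 and 61.9% without large library 2. Depth limits what can be seen at low abundance, since 0 counts allow 1.23 CPM in the shallowest library. Tests of gene lists and sums over gene names or parental copies were not run, because the rows carry no gene names.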

Other observations

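The edgeR fit with the replicate block was planned, while its use to explain the few small p-values, and the thinning, split and neighbour tests, were chosen after the patterns had been seen. For thinning the outcome was not yet known when the test was set.

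On average the 2 libraries of a replicate number resembled each other more than libraries of the same growth group did, though not for number 2 (r = 0.85, against 0.87 between large libraries 2 and 3). Library depth is argued against: with all libraries thinned to 2434421 counts, replicate number still took 69.1% of the sum of squares or more in each of 20 draws, against 68.4% unthinned. Preparation or sequencing shared by the 2 libraries of a number, and fish families, ponds or sex makeup shared by them, cannot be told apart: either could give the 68.4%, and the labels do not say what a number stands for. No biological explanation was tested.

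Fewer coding sequences fell below an unadjusted p of 0.05 than an even spread would give, 1.07% against 5%, when large and small were compared without the block. The count behind it, 194, was 438 without small library 1, 383 without large library 1, 441 without both and 117 without large library 2, so its size depends on single libraries. A candidate explanation is that variation between replicate numbers, which both groups contain, was counted as spread within groups. With the block the share was 5.0% in edgeR, while over the same coding sequences it went from 1.22% to 3.76% in DESeq2 and from 2.45% to 8.77% in voom, and over all p-values of DESeq2 with the block it was 2.15%. The share thus lay nearer to the even 5% with the block in edgeR and DESeq2 but above it in voom, which leaves the explanation open.

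The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. In edgeR the real split gave 0 calls, which all 10 reach by construction, and the highest other gave 1, while in DESeq2 without the block all 10 gave at least the 1 call of the real split and the highest other gave 1203. That split put both libraries numbered 1 with large library 2, which points to the structure by replicate number. Only 4 splits, the real one included, separate the libraries of every number, again too few for a share under 0.05. Among these, 1 of 4, the real one, reached the 51 calls of DESeq2 with the block (highest other 17), and 1 of 4, again the real one, reached the 907 coding sequences under an unadjusted p of 0.05 in edgeR with the block (highest other 602).

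Coding sequences with consecutive running numbers varied together more often than random pairs. Among 11045 pairs of consecutive numbers, 13.3% correlated above 0.8 across the 6 libraries, against a mean of 8.39% and a maximum of 8.75% in 100 random pairings. At a distance of 10 numbers the share was 9.30%, and at a distance of 100 it was 8.24%. Neighbouring rows of the table are therefore not fully independent of each other in tests across coding sequences. No explanation was tested.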
